A study of Oryza sativa Japonica Group with 31 samples.

How the data were processed

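The series holds 31 libraries of rice leaf, of which 4 are RNA-seq libraries, 2 from control seedlings and 2 from seedlings kept at 4 °C for 24 h. Per the labels' protocols, seedlings were grown at 28 °C by day and 22 °C by night with 12 h of light and 12 h of dark, and messenger RNA was enriched from total RNA with oligo(dT) beads. The replicates are called biological in the labels. The deposited values are FPKM (fragment counts scaled by locus length and by mapped fragments) in 1 column for control and 1 for cold. Whether a column holds 1 library, the merged reads of both or a mean is not given in the sources used here. FastQC, Trimmomatic 0.39, HISAT2 2.1.0, featureCounts 1.6.4, Trim Galore 0.4.3, Bowtie and SAMtools are named together for all assays, per the submitters' processing notes, without saying which step or assay each served. The genome build, the annotation and the handling of strand and of reads with several positions are not given in the sources used here. FPKM divides out length and depth, so a few abundant transcripts can shift all other values of a column, and reads shared by near-identical or overlapping loci cannot be traced.

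A limma test of 2 against 2 libraries was fixed before the data were examined, together with the provision that no test is made if the table holds 1 value per treatment. It did, so no test was run and values are described. The filter planned for 4 libraries became a mean of at least 1 FPKM over the 2 columns, which kept 20876 of 55801 loci and left out 34925. Fold changes are differences of log2(FPKM + 1), with a pseudocount of 1, except where a ratio of FPKM is named. The 2-fold limit was planned. The larger limits, the classes of level, the chromosomes and the neighbouring loci were chosen after the columns had been seen.

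The locus identifiers were looked up in a RefSeq gene table of assembly ASM3414082v1 with 39387 genes, in which 1 identifier was found, LOC_Os01g19850, paired with LOC4323905. It was listed at 0.182 FPKM in control and 0.198 FPKM in cold. The 35 gene lists fixed in advance were not used. Some of them also held locus identifiers, written from memory. Their rule set all lists aside if no reference named the identifiers, and only 1 was named. The rule for single loci took those with the largest log2 fold change in each direction among loci with a mean of at least 10 FPKM. Its conditions on a test and on a descriptive gene name could not be applied, values above 0 in both columns were required, and 2 loci were taken per direction. No coordinates are given, since the build is not known.

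Each chromosome's median was set against 1000 shuffles of fold changes between loci of the same level class, with class edges at 1, 3, 10, 30, 100, 300 and 1000 FPKM. Pairs of loci a fixed number of places apart in the order of the identifiers were compared by Spearman's rho after subtracting the median of each level class, again with 1000 shuffles, and runs of loci with 100. Because neighbouring loci were correlated, chromosome medians were also set against 1000 shuffles of blocks of 20 consecutive kept loci, after subtracting the level class medians. The block shuffles were added after the data had been seen. A relative depth, which holds if each column has a single depth, came from the cold to control ratios of 3541 loci above 0 and under 0.3 FPKM in both columns, with a tolerance of 0.02%. Of these, 56 lay at the ratio 1.2427 and 93 at 6 other small whole-number multiples or fractions of it, where windows elsewhere held 0.3 on average. This depth is relative. No count, interval or detection limit can be derived from it.

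The scripts were tested on simulated data with Poisson counting, assumed lengths and assumed depths. For cold against control, 20851 simulated loci passed the floor. The 4-fold changes were planted in 200 loci of at least 5 FPKM in control, and 100% of them were recovered past the 2-fold limit. No change was planted in weaker loci, where the pseudocount shrinks folds more, so their recovery was not tested. A simulated relative depth of 1.24 was recovered from 2783 loci. For neighbouring loci, a planted correlation of 0.3 was recovered as 0.28, and with none planted the value was −0.0074, over 20851 loci.

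Alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, rescaling each column to the same sum (TPM), median-of-ratios scaling on the FPKM and quantile normalization. A filter on either column and a fold without a pseudocount were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The DRIP-seq, ChIP-seq and DNase-seq libraries, 27 in all, were not used here.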

Results

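Leaves of seedlings of Nipponbare, the japonica rice cultivar used as the reference for the rice genome, were profiled with and without cold. The series addresses how R-loops, structures in which an RNA strand pairs with DNA and displaces the other DNA strand, relate to the transcription of genes that respond to cold in rice. Of its 31 libraries, 4 are RNA-seq libraries, and the values described here are of that assay. Whether all 4 entered the values is not known. There were 2 from control seedlings and 2 from seedlings held at 4 °C for 24 h from day 13, while the controls stayed at 28 °C by day and 22 °C by night. The other 27 libraries were not used here. They comprised 10 DRIP-seq libraries, in which DNA-RNA hybrids are captured with an antibody, 1 RNase H control of that assay, 12 ChIP-seq libraries for 6 histone marks, 2 ChIP-seq inputs and 2 DNase-seq libraries.

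The RNA-seq values came as 1 FPKM column for control and 1 for cold, so each value below is the authors' value for a treatment and has no replicate error. No difference between the columns could be set against a spread between replicates, and no p-value is given. The table listed 55801 loci on 12 chromosomes. Of these, 28807 were above 0 in both columns, 2837 only in control and 1978 only in cold, and 22179 were listed at 0 in both. At least 1 FPKM was listed for 20817 loci in control and 19907 in cold. The summed FPKM was 584870 in control and 554475 in cold. The number of reads behind a column is unknown. The most frequent cold to control ratio among low values was 1.24, held by 56 of 3541 pairs. If each column has a single depth, which was not settled, this puts the cold depth at 0.805 of the control depth.

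The comparison of cold with control asks which loci differ in transcript level after 24 h at 4 °C. Among loci with a mean of at least 10 FPKM, LOC_Os03g08500 on chromosome 3 was listed at 0.875 FPKM in control and 337.5 FPKM in cold, a ratio of 386. LOC_Os07g34570 on chromosome 7 was also higher in cold, at 23.1 FPKM in control and 3356 FPKM in cold, a ratio of 145. In the other direction, only loci above 0 in both columns were taken. LOC_Os03g54130 on chromosome 3 was listed at 84.0 FPKM in control and 2.33 FPKM in cold, 35.98-fold lower. LOC_Os04g59440 on chromosome 4 was 23.4-fold lower, at 252 FPKM in control and 10.8 FPKM in cold. On the log2(FPKM + 1) scale, which understates the difference of low loci, these 4 loci differed by 7.50, 7.12, −4.67 and −4.42. The value of LOC_Os03g08500 depended on the pseudocount, at 8.59 with none and 5.87 with 5, and that of LOC_Os03g54130 was −3.60 with 5. The direction of all 4 was the same under each of the 3 scalings tried. These moved the median log2 fold change by at most 0.29, too little to turn differences of this size. Requiring values above 0 left out no higher locus. It did leave out loci listed at 0 in cold and at 88.7 and 116 FPKM in control, which fell further on the log2(FPKM + 1) scale. The table does not pair its locus identifiers with gene names, and the chromosome is the one written in the identifier.

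The most abundant transcripts of the treatments were not the same. The locus with the highest control value, on chromosome 11, was listed at 7863 FPKM in control and 2800 FPKM in cold, a 2.81-fold lower level. The locus with the highest cold value, on chromosome 1, was listed at 342 FPKM in control and 5719 FPKM in cold, 16.7-fold higher. The top 100 loci held 23.3% of the control FPKM and 20.1% of the cold FPKM, and 65 loci were in both top lists. The top 10 loci held 7.11% in control and 6.01% in cold. Among the 38 loci with a mean of at least 1000 FPKM, 9 were at least 2-fold higher in cold and 13 at least 2-fold lower.

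Loci near 0 in one column and well above it in the other lay mostly on the side of cold. Of 9314 loci with at least 10 FPKM in cold, 38 were under 0.5 FPKM in control, and 0 of them were listed at 0. Of 10019 loci with at least 10 FPKM in control, 4 were under 0.5 FPKM in cold. Of these 4, 3 were listed at 0 in cold. Their control values were 15.7 FPKM on chromosome 5, 88.7 FPKM on chromosome 6 and 116 FPKM on chromosome 9.

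Across the 20876 loci with a mean of at least 1 FPKM, 14256 (68.3%) differed by less than 2-fold on the log2(FPKM + 1) scale. At least 2-fold higher levels in cold were found for 2617 loci and at least 2-fold lower levels for 4003, so that 39.5% of the loci past this limit were higher. With larger limits the order turned. At 4-fold, 806 loci were higher and 449 lower, at 8-fold 247 were higher and 29 lower, and at 16-fold 80 were higher and 6 lower. Part of this turn comes from the scale. With a pseudocount of 1, loci with a mean of 1 to 3 FPKM cannot reach 8-fold. At 2-fold, 315 of them were higher and 802 lower. The 2-fold split depended on the pseudocount and on the scale set between the columns. With a pseudocount of 5, 1663 loci were higher and 1618 lower (50.7% higher). Median-of-ratios scaling moved the median log2 fold change of these loci by 0.29 and gave, among the 20832 loci then past the floor, 3766 higher and 2285 lower (62.2% higher). Quantile normalization moved it by 0.16 and gave 3097 higher and 2958 lower (51.2% higher). Rescaling both columns to the same sum moved it by 0.05 and gave 3238 higher and 4367 lower (42.6% higher). That rescaling also raises every value against the floor and the pseudocount, and its counts are over 22666 loci. At 8-fold, higher loci outnumbered lower ones under all 3, with 338 against 19, 277 against 27 and 335 against 43. Without a pseudocount the 8-fold counts, over loci above 0 in both columns, were 495 and 241. That is a ratio of 2.054, against 8.517 with a pseudocount of 1.

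**Figure D1:**
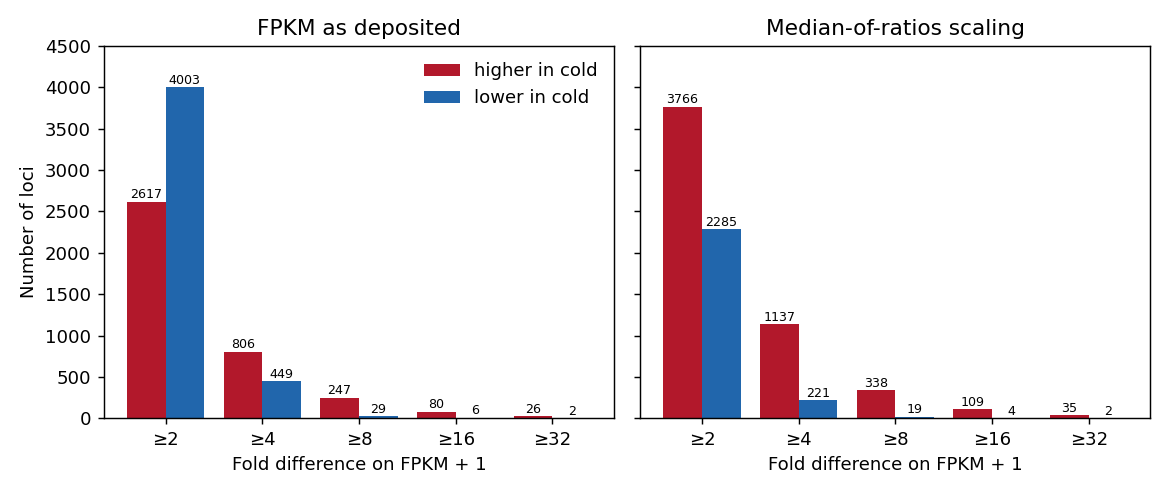
Number of loci (vertical axis) at least 2-, 4-, 8-, 16- or 32-fold higher (red) or lower (blue) in cold than in control on the FPKM + 1 scale, for the values as deposited (left) and after median-of-ratios scaling (right). As deposited, lower loci outnumber higher ones at 2-fold (4003 against 2617) and higher loci outnumber lower ones at 8-fold (247 against 29), while after scaling higher loci outnumber lower ones at 2-fold as well (3766 against 2285).

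Over the same loci the log2 fold change had a median of −0.27 with quartiles of −0.84 and 0.41. The correlation between the columns, taken across genes, which are not independent replicates, was 0.80 (Spearman's rho) and 0.81 (Pearson's r of the log2 values). The difference varied with the level of a locus. Weakly expressed loci, with a mean of 1 to 3 FPKM (4289 loci), had a median log2 fold change of −0.40, with 7.34% at least 2-fold higher and 18.7% at least 2-fold lower. Without a pseudocount, over loci above 0 in both columns, the median of this class was −0.65 and that of loci of 30 to 100 FPKM was −0.04. Loci of 30 to 100 FPKM (3107 loci) had a median of −0.04, with 20.95% higher and 16.96% lower. The 38 loci of 1000 FPKM or more had a median of −0.77. Median-of-ratios scaling, which centres the cold to control ratios of loci above 0 in both columns, turned the sign of 4 of the 7 classes. Their medians became 0.19 at 10 to 30 FPKM, 0.35 at 30 to 100, 0.29 at 100 to 300 and 0.13 at 300 to 1000. The classes of 1 to 3 FPKM (−0.19), 3 to 10 FPKM (−0.081) and 1000 FPKM or more (−0.42) stayed below 0.

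**Figure D2:**
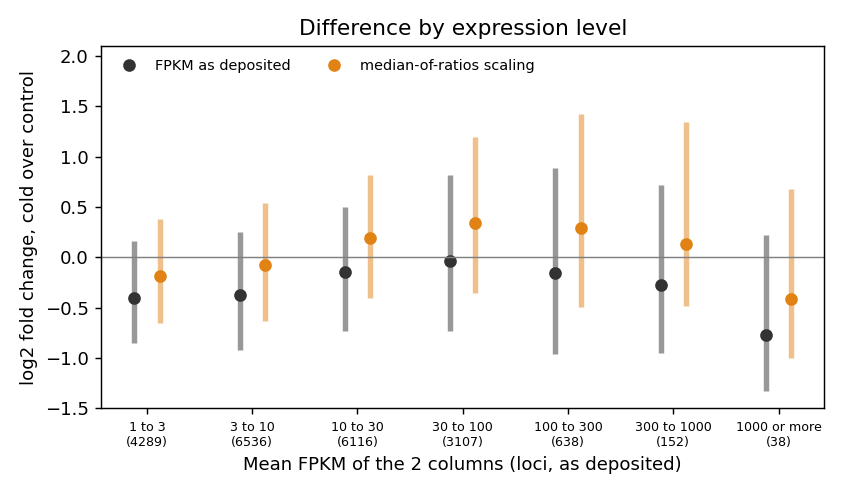
Log2 fold change of cold over control on the log2(FPKM + 1) scale (vertical axis) by the mean FPKM of the 2 columns (horizontal axis, number of loci as deposited in brackets), with points for medians and bars from the lower to the upper quartile across loci, as deposited (grey) and after median-of-ratios scaling (orange). The median goes from −0.40 at 1 to 3 FPKM to −0.04 at 30 to 100 FPKM and −0.77 at 1000 FPKM or more as deposited, and from −0.19 to 0.35 and −0.42 after scaling.

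Chromosomes differed little from one another. Their median log2 fold changes lay between −0.40 on chromosome 12 and −0.22 on chromosome 1, around the median of −0.27 of all loci, and are set against it since a scaling shifts the median of all loci. When loci were shuffled 1000 times between chromosomes within classes of similar level, chromosome 1 lay above the range that held 95% of its shuffled medians, from −0.31 to −0.24. Chromosome 12 lay below its range of −0.34 to −0.23 and below the lowest of its shuffled medians, −0.38. Chromosome 11, at −0.38, lay below its range of −0.36 to −0.23. Chromosome 7, at −0.333, lay just below its lower limit of −0.326, and the other 8 chromosomes lay within their ranges. On chromosome 1, 14.8% of loci were at least 2-fold higher in cold, above its shuffled range of 11.6% to 13.7%. The shares on chromosome 11 (10.6%) and chromosome 12 (10.9%) lay within their ranges, and that on chromosome 7 (10.7%) lay below its lower limit of 11.1%. At least 2-fold lower levels were found for 22.6% of loci on chromosome 11 and 21.8% on chromosome 12, above upper limits of 21.7% and 21.4%. The median of chromosomes 11 and 12 together minus that of the others was −0.13, and it was −0.058 with a pseudocount of 5 and −0.019 without the filter on low values. These shuffles treat loci as independent, and neighbouring loci are not. The level class medians were then removed and blocks of 20 consecutive loci were shuffled instead. Chromosome 1 (0.0498, upper limit 0.0403) and chromosome 12 (−0.112, lower limit −0.0732) lay outside their ranges, and chromosomes 7 and 11 lay within them. Neither passed the extremes of its block shuffles, the highest 0.0707 for chromosome 1 and the lowest −0.115 for chromosome 12. No allowance was made for comparing 12 chromosomes. The shuffles describe loci within these columns and do not stand for replicates.

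**Figure D3:**
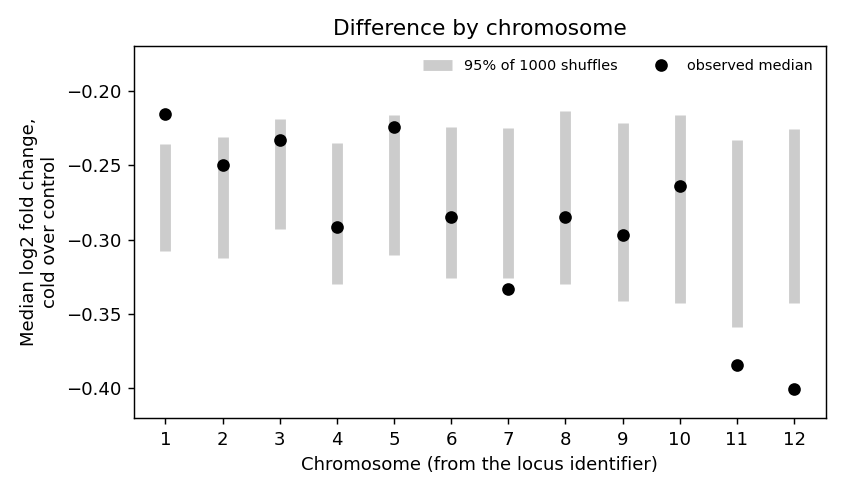
Median log2 fold change of cold over control on the log2(FPKM + 1) scale (vertical axis, which does not start at 0) for each of the 12 chromosomes named in the locus identifiers (horizontal axis), with grey bars for the range of 95% of 1000 shuffles of loci between chromosomes within level classes. Chromosome 1 (−0.22) lies above its bar, and chromosomes 7 (−0.33), 11 (−0.38) and 12 (−0.40) lie below theirs. When blocks of 20 loci were shuffled, chromosomes 1 and 12 stayed outside their 95% ranges, though within the extremes of those shuffles.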

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

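The filter on either column and the fold without a pseudocount were chosen after the data had been seen. Of 108 values recomputed under the alternatives, 85 stayed within the limits set, 22 moved and 1 reversed. The limits were a 1.5-fold change for counts, 10 percentage points for percentages and 0.03 for rho. For log2 fold changes they were 0.1 for medians and 0.5 for named loci. A filter leaves the fold of a named locus as it is, so part of the 85 was fixed in advance. Neither a filter nor a pseudocount can turn the direction of a named locus. The direction of the 4 named loci was kept under every alternative, though the log2 fold change of LOC_Os03g08500 (7.50) ranged from 5.87 to 8.59 and that of LOC_Os03g54130 was −3.60 with a pseudocount of 5. Kept too was the excess of higher over lower loci at 8-fold, and rho of adjacent loci stayed between 0.132 and 0.154. With a pseudocount of 5, 1663 loci were at least 2-fold higher and 1618 lower (50.7% higher), 102 and 8 passed 8-fold, and the median was −0.165. With 0.1, 472 and 175 passed 8-fold, and with none 495 and 241 of the loci above 0 in both columns. A smaller pseudocount shrinks weakly expressed loci less. A mean of at least 5 FPKM left 2605 loci at least 2-fold lower, having fewer loci. Median-of-ratios scaling reversed the median, to 0.029, with 2285 loci at least 2-fold lower, 19 lower at 8-fold and 62.2% higher at 2-fold. It centres the cold to control ratios of loci above 0 in both columns, so a median near 0 follows from the scaling itself. Quantile normalization gave a median of −0.10 and 51.2% higher. Which scale is right was not tested. With no filter the median was −0.076, and chromosomes 11 and 12, grouped after their medians were seen, lay −0.019 from the others, against −0.13 with the filter, as loci near 0 then enter with folds near 0. No paired analysis was possible because each treatment has 1 column, with no replicate numbers. For the same reason the fits without a variance trend, without each replicate, with a stricter adjusted p or against a minimum fold were not run. The gene list tests lacked both replicates and a reference that names the loci. The unknown depth leaves the counting error of single loci unknown.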

Other observations

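Tests of the scale between the columns, of the pseudocount and of averaged libraries were chosen only after the result had been seen, and the level classes were known when the test on abundant loci was set.

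Loci with large differences lay side by side more often than shuffled ones. Runs of at least 3 consecutive loci that were all at least 2-fold higher in cold numbered 49, against at most 25 in 100 shuffles within level classes. Runs of loci at least 2-fold lower numbered 76, against at most 58. The longest run held 5 loci in either direction, no longer than the longest in the shuffles, 5 for higher and 8 for lower loci.

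Fold changes of neighbouring loci were weakly correlated among the kept loci. Over 11825 adjacent pairs Spearman's rho across loci was 0.157 before and 0.1481 after the level trend was removed, above the highest of 1000 shuffles (0.031), which argues against similar levels of neighbours as the whole cause. The correlation was 0.08 for 10665 pairs 2 places apart and 0.04 for 10247 pairs 3 places apart, both above their highest shuffles (0.033 and 0.031), and at 5 places (0.01547) and 20 places (0.01594) it lay within the shuffles (highest 0.033 and 0.041), so reads shared by overlapping neighbours or by near-identical copies in a row cannot be told apart from a shared response, lacking coordinates and sequences. For 2130 pairs 2 places apart around a locus under 0.1 FPKM, rho was 0.09086 against at most 0.0755 in shuffles. For these pairs, run-on reads counted at the middle locus are thus not needed for the correlation. Reads that ran through that locus could have gone uncounted, since the handling of strand and of reads with several positions is not given. Run-on transcription therefore stays open. A regional response to cold may contribute and stays a hypothesis.

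At 8-fold, 247 loci were higher in cold and 29 lower. Under the 3 scalings higher loci outnumbered lower ones by at least 7.791 to 1. All 3 shift the cold column upward, which favours higher loci, so they could not have removed the excess and decide nothing on scale. A scale difference of the opposite sign, which none of them removes, would have to reach a log2 shift of −0.50 to make the counts equal, and no value decides on it. Among 3935 loci with a mean of at least 30 FPKM, 120 were higher and 19 lower, a ratio of 6.316, which argues against counting noise of weakly expressed loci. Without a pseudocount the ratio over kept loci above 0 in both columns was 2.054, and among loci of at least 30 FPKM it was 6.80 (136 higher, 20 lower). With a pseudocount of 1 the ratio over all kept loci was 8.517, so the size of the excess depended on the pseudocount. An excess remained without one. The limit for this comparison was set when the ratio of 2.054 was known, so the comparison describes the values and is no test. That scale difference, a response to cold and a peculiarity of a single library stay open.

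The ratios of low values bear on what a column holds. The most frequent cold to control ratio, 1.2427, held 56 of 3541 pairs. The next one that is no small whole-number multiple or fraction of it, 1.2468, held 10, which is 0.1786 of the first. In simulated columns that value was 0.84 when each was the mean of 2 libraries of different depth and 0.0035 with 1 depth per column. The depths simulated were assumed, and the observed value lay far from both, so it was not settled whether a column is a single library, merged reads or a mean of libraries. No biological explanation was tested.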
